A study of Rattus norvegicus with 6 samples.

How the data were processed

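Total RNA from the left ventricle of 6 rats was measured, 3 labelled normal and 3 labelled diabetic, with 1 single-colour Affymetrix array per heart. The design text counts the animals as separate rats. The labels give neither the way diabetes was produced nor its duration, the strain, the sex, the feeding state or the time of sampling, and they describe the RNA and labelling steps only as the manufacturer's standard ones.

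The deposited table holds 1 signal intensity per probe set and array, on a linear scale. The software and normalization that the authors used to make these intensities are not given in the sources used here. The mean after trimming 2% of probe sets from each end was 500.2 on every array, so the deposited intensities had been scaled to a common level. By a rule set before the data were examined (trimmed means within 10% of each other), they were used as deposited. Signals ran from 0.2 to 72999.3, and array medians from 180.3 to 191.3. No detection calls were used here, so background is known only through the low end of the signals, and the number of arrays limits the precision.

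The array holds 15923 probe sets. The 57 control probe sets were left out of the tests, and 15866 remained. Names came from the array's annotation, updated through a rat gene table (assembly name GRCr8, used for names only). Of these probe sets, 12783 had 1 gene, 312 had several and 2771 were unnamed here. Of the single-gene probe sets, 12748 matched the gene table by gene number, 2 by accession, and 33 kept the annotation's symbol. The update changed 1 symbol. The named probe sets covered 10411 genes.

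Intensities were turned into log2(value + 16). Fold changes are on that scale, which understates the change of dim genes. A probe set was tested if its mean over all 6 arrays lay above the 40th percentile, a filter blind to group, which kept 9519 and left out 6347. Diabetic and normal arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided). Changed means a Benjamini-Hochberg adjusted p under 0.05 over the tested probe sets. Values after ± are SD for signals (n = 3 per group) and standard errors for log2 fold changes. With 3 against 3 arrays an exact permutation test of one gene cannot go below p = 0.1, so all calls rest on limma's model, which shares the spread across probe sets.

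Before the data were examined, 45 gene lists were fixed, covering pathways and cell type markers that fit a rat ventricle in diabetes. Each list with at least 4 tested genes was tested with limma's camera at a preset correlation of 0.01, using the brightest tested probe set of each gene, which left 40 lists. Camera compares a list's genes with all other genes. The same lists were tested with an estimated correlation and with fry. A member is counted as risen or fallen by its own adjusted p over all tested probe sets, and the count adjusted over the list alone is given beside it.

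The genes to name were also fixed by rule. They are the 12 largest rises and 12 largest falls among changed probe sets with 1 gene and no overlap between groups, up to 4 members per list with the smallest p, a panel of 30 genes studied in diabetic heart, and the Gapdh and beta-actin control probe sets. From the panel, Ppara lay below the dim filter. All tested panel genes are reported, and list members that did not pass are named only in part. Genes outside the rule are said to be chosen after their values were seen, or to belong to a test given below.

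The code was tested on simulated data of 9519 probe sets with 200 planted changes. It recovered 8% of planted changes of 0.5 on the log2 scale, 86% of those of 1, and 100% of those of 2 and of 3. Of its 159 calls, 12 were false, somewhat more than a threshold of 0.05 aims for. In a simulated list test, the 1 planted list was recovered, and 1 of the other lists was called. The simulated noise was independent between probe sets, so these runs cannot show how the list test behaves with correlated genes. No pair of arrays held identical values at more than 25 probe sets.

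The alternatives tried were pseudocounts of 1 and 64, quantile and median scaling, no filter and a filter at the 60th percentile, an intensity trend, a robust prior, array weights, the replicate number as a block, each array left out, a threshold of 0.1, and other list tests. An unfiltered fit with an intensity trend and Fisher's exact enrichment of the lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.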

Results

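Gene expression was measured in the left ventricle of 3 normal and 3 diabetic rats, with 1 Affymetrix array per animal. The comparison between the groups asks which transcripts differ in the heart in diabetes. Pairs of arrays within a group correlated at r = 0.967 to 0.974 across tested probe sets (6 pairs), and pairs between groups at 0.937 to 0.959 (9 pairs). Probe sets are not independent replicates. The first principal component held 44.5% of the variance and separated the groups, with normal arrays at -13.8, -14.4 and -27.6 and diabetic arrays at 14.7, 22.0 and 19.1. On that component normal 3 lay farthest from the others of its group. On the second, with 16.8% of the variance, diabetic 1 did so, at 23.0 against -10.1 and -11.0 for diabetic 2 and 3.

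The diabetic ventricles had far more transcript for atrial natriuretic peptide and for beta-myosin heavy chain. They had less for alpha-myosin heavy chain, fibrillar collagens and the ketone-using enzymes Oxct1 and Bdh1. The largest rise of a named gene was that of Acot1, a cytosolic acyl-CoA thioesterase, from a mean signal of 44.8 ± 17.9 to 655 ± 382 (SD, n = 3 per group), a log2 fold change of 3.34 ± 0.39 (SE, limma adjusted p = 0.00588). Nppa, the precursor of atrial natriuretic peptide, rose from 3671 ± 359 to 25244 ± 4960.5, which is 6.78-fold (log2 2.76 ± 0.18, adjusted p = 0.00087). Nrep fell furthest, from 1350.3 ± 332 to 173 ± 70.8 (log2 -2.89 ± 0.27, adjusted p = 0.00189). In all, 274 of 9519 tested probe sets changed, of which 143 rose and 131 fell. They named 221 genes, 114 risen and 107 fallen, while 36 of the probe sets had no single gene name. A further criterion of more than 2-fold was met by 86 risen and 68 fallen probe sets. The groups did not overlap at 2449 probe sets (25.7%), where chance gives 10%. The count depended strongly on the filter for dim probe sets, since only 18 changed without it, 12 of them among the 274 (Nppa, Ckb, Nrep, Cbr1, Col3a1, Col15a1 and Serpinh1 among the genes named here, but not Acot1 or Myh7). It fell to 100 without normal 3 and to 100 without diabetic 2, to 138 without normal 2 and to 135 without diabetic 3, and it was 527 with an intensity trend.

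**Figure D1:**
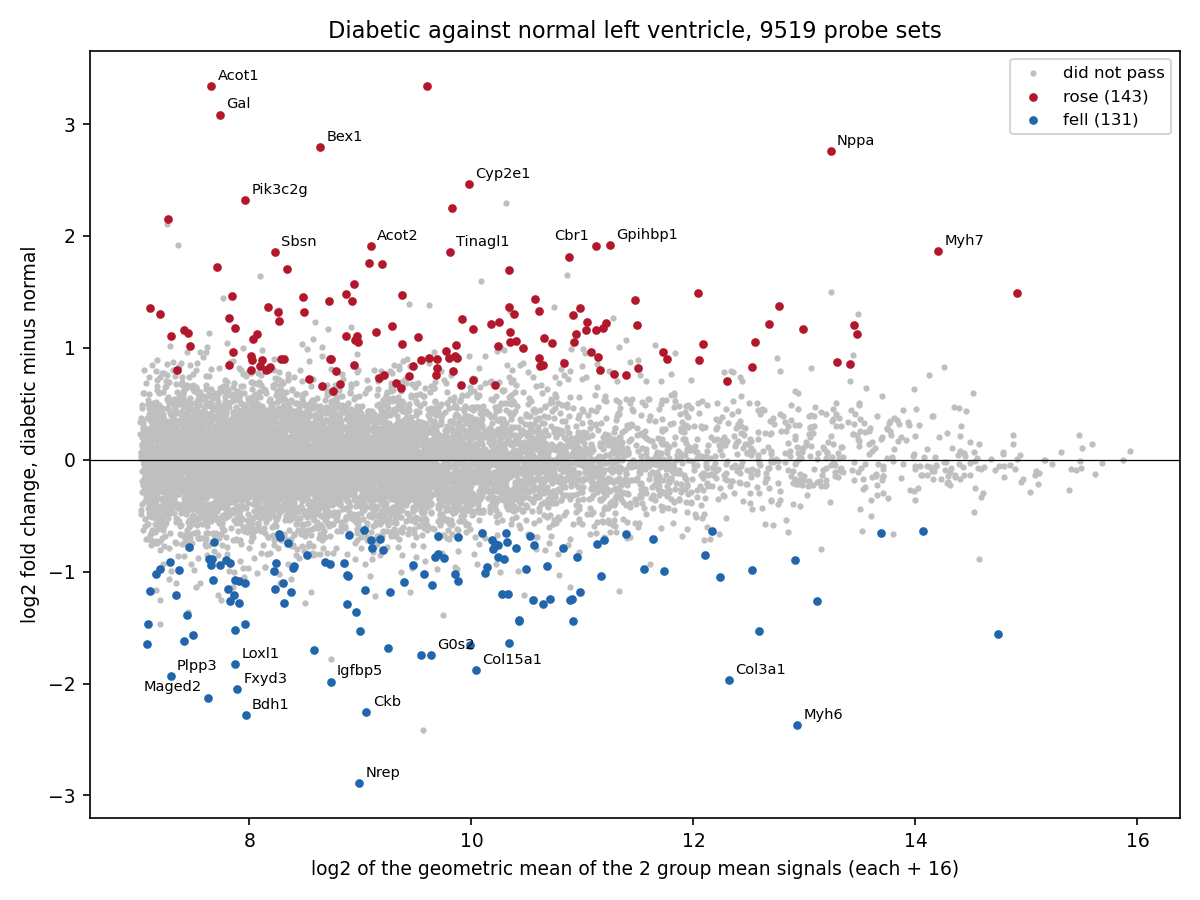
Log2 fold change of diabetic over normal ventricle against log2 mean signal for each tested probe set, with the 143 that rose in red, the 131 that fell in blue and the others in grey. The named genes are the 12 largest rises and 12 largest falls fixed by rule, with Nppa and Myh7 standing apart at high signal.

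Among the other large rises, Gal, which encodes the neuropeptide galanin, had a log2 fold change of 3.08 ± 0.60 (adjusted p = 0.0324) and Bex1 one of 2.79 ± 0.35 (adjusted p = 0.00646). Pik3c2g, a class II phosphoinositide 3-kinase, rose by 2.32, Cbr1, a carbonyl reductase, by 1.91, Tinagl1 by 1.86 and Sbsn by 1.86. Among the falls, Ckb, the brain-type creatine kinase, changed by -2.26 ± 0.16 on the log2 scale, from 1149 ± 179.8 to 226 ± 16.9 (adjusted p = 0.00087). Maged2 changed by -2.13, Fxyd3, a regulator of the sodium pump, by -2.05 and Igfbp5 by -1.98. Plpp3, a lipid phosphatase, changed by -1.94 at its dimmest probe set only, and its 2 brighter ones were at -0.58 (adjusted p = 0.131) and -0.62 (adjusted p = 0.0881). Of the 24 genes taken as largest changes, 17 passed the threshold with any 1 array left out. The other 7, each with the arrays whose loss ended the call and the highest adjusted p, were Gal (lost without normal 2 or 3 or diabetic 1 or 2, at most 0.0963 without diabetic 2), Cyp2e1 (lost without normal 2 or diabetic 1, 2 or 3, at most 0.128 without diabetic 2), Gpihbp1 (lost without diabetic 1, 2 or 3, at most 0.084 without diabetic 3), Acot2 (lost without normal 2 or diabetic 1 or 3, at most 0.0618 without diabetic 3), Bdh1 at the probe set with the larger fall (lost without normal 1, 2 or 3 or diabetic 1, at most 0.129 without normal 3), Loxl1 (lost without normal 1, 2 or 3 or diabetic 2, at most 0.133 without normal 3) and G0s2 (lost without normal 1, 2 or 3 or diabetic 1 or 2, at most 0.119 without diabetic 2). On the log2 scale Gal moved to 2.43 and Cyp2e1 to 1.71 without normal 3, and Bdh1 to -1.62 without diabetic 3.

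The myosin heavy chains of the contractile filament moved in opposite directions. Myh7, the slow beta form, rose at both of its probe sets, from 18541 ± 4889 to 51191 ± 7019 at the brighter (log2 1.49 ± 0.21, adjusted p = 0.00888) and by 1.86 at the other. Myh6, the fast alpha form, fell at both, from 45677 ± 7167 to 16378 ± 6423 (log2 -1.55 ± 0.29, adjusted p = 0.0281) at the brighter and with a log2 fold change of -2.37 at the other. With 1 array left out, the brighter Myh6 probe set stayed at -1.81 to -1.20 (lost without normal 1, 2 or 3 or diabetic 1, at most 0.0769 without normal 1). Of 5 tested probe sets for Myh1, named for a fast skeletal form, 3 rose (log2 1.13, 1.21 and 1.17), while the others were at 0.79 (adjusted p = 0.0786) and -1.02 (adjusted p = 0.21). Since these myosin genes are close copies of each other, the Myh1 signal is uncertain. Of the 16 tested stress-associated fetal cardiac genes, Nppa and Myh7 rose and Adra1b, an alpha-1 adrenergic receptor, fell (log2 -1.20 ± 0.17), and adjusted over the list alone the count was the same. The list as a whole lay above other genes (median log2 0.30, camera adjusted p = 0.00422, but adjusted p = 0.353 with an estimated correlation), and without diabetic 2 its adjusted p was 0.0713. Nppb, the B-type natriuretic peptide, was at 9658 ± 896 in normal and 10918 ± 4289.9 in diabetic arrays (adjusted p = 0.856). In the list of 24 sarcomere and cytoskeleton genes, Myh7 rose, while Myh6 and Fhl2, a sarcomere-associated protein (lost whichever array was left out, at most 0.134 without diabetic 3, and -0.65 with an adjusted p of 0.0732 at its other probe set), fell, with the same count adjusted over the list alone. That list did not shift (adjusted p = 0.896), nor did the 14 thyroid hormone responsive cardiac genes (adjusted p = 0.642), where Myh7 rose and Myh6 and Slc2a4 fell, with 1 risen and 3 fallen adjusted over the list alone. Of 8 atrial cardiomyocyte markers only Nppa passed, also adjusted over the list alone, though all 8 had positive log2 fold changes (median 0.40, camera adjusted p = 0.00422, but adjusted p = 0.265 with an estimated correlation). Of the other atrial markers, Myl7 differed by 0.17 ± 1.00 on the log2 scale, Sln by 1.64 ± 1.18 (0.57 without normal 2 and 2.55 without normal 3) and Myl4 by 0.43 ± 0.67 (SE over arrays). The Myl7 signal was 812, 162 and 99.9 in normal 1, 2 and 3, so its small difference rested on normal 1. Myl7 and Myl4 lie outside the naming rule and belong to a test given below. Nppa, Myl7 and Myl4 are also in the fetal cardiac list.

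**Figure D2:**
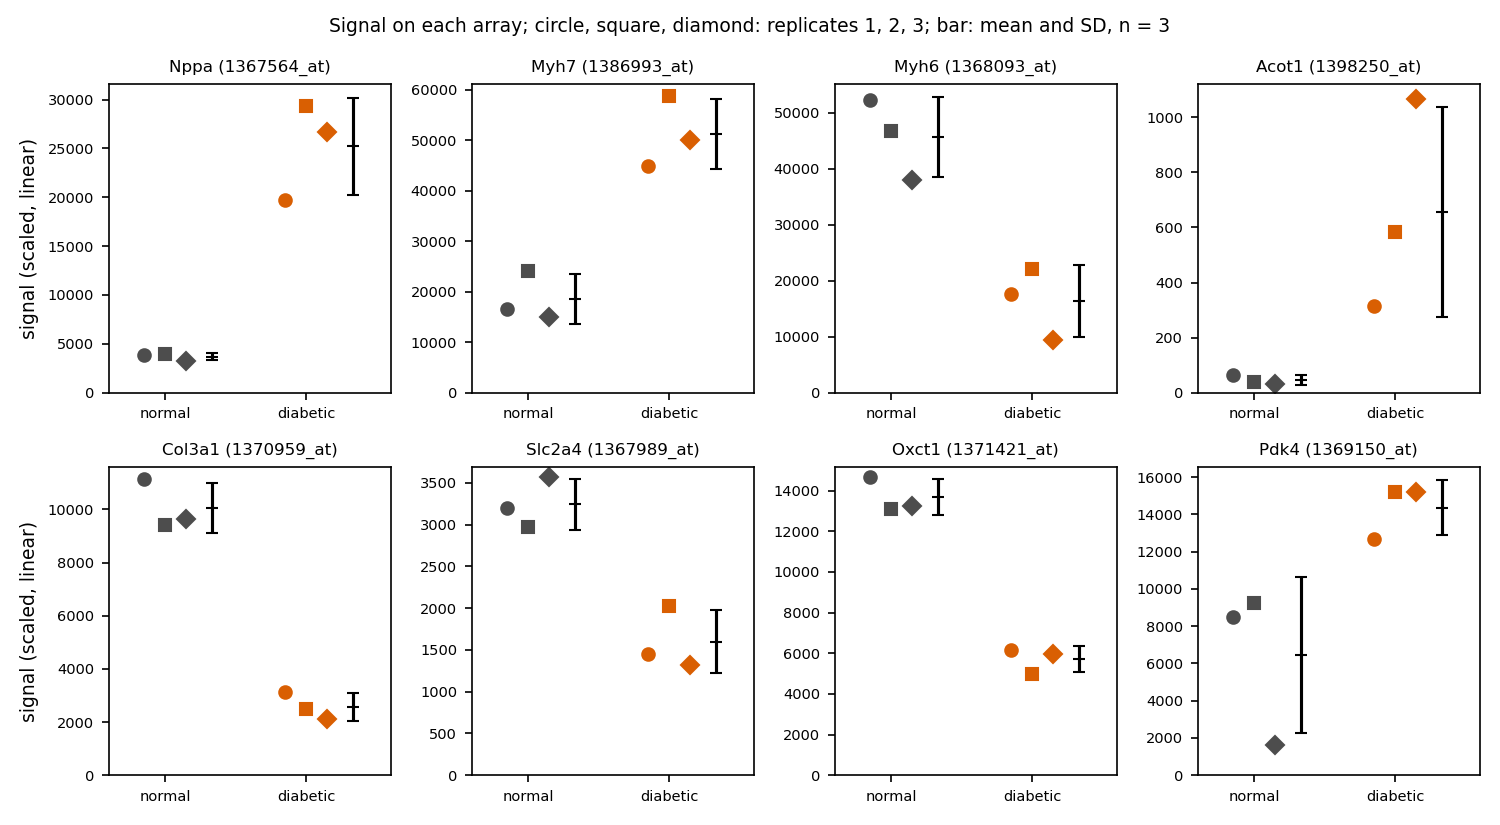
Signal on each of the 6 arrays for 8 genes of the fixed naming rule (linear axis from 0, normal in grey, diabetic in orange, bars for mean and SD, n = 3). These 8 were chosen for display after their values were seen. Diabetic arrays lie outside the normal range for each gene, and for Pdk4 normal 3 lies at 1642 against 8462 and 9237 in the other normal arrays.

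Genes of fatty acid oxidation lay higher as a group by camera at its preset correlation, with a median log2 fold change of 0.33 (camera adjusted p = 3.05e-05, but adjusted p = 0.419 with an estimated correlation). Of 32 tested fatty acid oxidation genes, 3 rose and none fell, and adjusted over the list alone 9 rose and 2 fell. The 3 that rose were Hadha, of the mitochondrial trifunctional protein (log2 0.85 ± 0.16), Eci1 (log2 0.87 ± 0.15) and Decr1 (log2 1.20 ± 0.21, adjusted p = 0.0201), the latter 2 needed for unsaturated fatty acids. In fits of 5 arrays, which also have less power, the log2 fold changes stayed at 0.79 to 0.96 for Hadha (lost without normal 1 or 3 or diabetic 2 or 3, at most 0.099 without normal 3), 0.78 to 0.94 for Eci1 (lost without normal 2 or 3 or diabetic 2 or 3, at most 0.0811 without normal 3) and 1.07 to 1.41 for Decr1 (lost without normal 2 or 3 or diabetic 2 or 3, at most 0.0779 without diabetic 2). Of 22 PPAR-alpha responsive genes, Acot1, Decr1 and Hadha rose and none fell, with 9 risen adjusted over the list alone (median 0.50, camera adjusted p = 5.72e-07, but adjusted p = 0.353 with an estimated correlation). Several of these lie in the oxidation list too. Pdk4, the kinase that shuts pyruvate dehydrogenase, was at 6447 ± 4179.6 in normal and 14364 ± 1466 in diabetic arrays, and Angptl4, an inhibitor of lipoprotein lipase, at 694 ± 544 and 2271 ± 667. Neither passed (adjusted p = 0.177 and 0.16), and for both every diabetic array was above every normal array. Their spread came largely from normal 3, which held 1642 for Pdk4 and 72.7 for Angptl4, against 927 and 1083 for Angptl4 in normal 1 and 2. Over all arrays the differences were 2.83-fold for Pdk4 and 4.91-fold (log2 2.30) for Angptl4, and without normal 3 they shrank to 0.69 and 1.12 on the log2 scale. Both lists kept their call without normal 3, with medians of 0.25 for fatty acid oxidation and 0.38 for PPAR-alpha responsive genes. Cpt1b, the carnitine palmitoyltransferase of muscle mitochondria, had an adjusted p of 0.326. Ucp3 had one of 0.998, and its difference near 0 also rested on normal 3, without which it was -0.66 on the log2 scale (adjusted p = 0.2), opposite to the PPAR-alpha list.

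Of 25 genes of fatty acid uptake, thioesterases and lipid storage, 4 rose and 2 fell (7 and 3 adjusted over the list alone). Acot2, the mitochondrial thioesterase, had a log2 fold change of 1.91 ± 0.31 and Gpihbp1, which anchors lipoprotein lipase in capillaries, one of 1.92 ± 0.35. Acot1 and Acot2 are close copies, so their signals may not be fully separate. Pnpla2, the main triglyceride lipase, rose (log2 1.49 ± 0.25, adjusted p = 0.0176) and G0s2, its inhibitor, fell (log2 -1.74 ± 0.36, adjusted p = 0.0396). With 1 array left out, Pnpla2 stayed at 1.19 to 1.67 (lost without diabetic 2 or 3, at most 0.069 without diabetic 2). Fabp5, a fatty acid binding protein chosen after its value was seen, was the other gene that fell (log2 -0.89 ± 0.16). This list did not shift as a whole (camera adjusted p = 0.0863, and 0.0177 without normal 1, 0.0287 without normal 2).

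Some transcripts for glucose, ketone and amino acid use fell, of which Oxct1 and the brighter Bdh1 probe set passed with any 1 array left out. Slc2a4, the insulin-regulated glucose transporter, fell from 3245 ± 305 to 1598 ± 379.8 (log2 -1.04 ± 0.19, adjusted p = 0.0249, lost without normal 1, 2 or 3 or diabetic 1 or 3, at most 0.0956 without normal 3). Its other probe set was at -0.93 (adjusted p = 0.103). Ldha fell (log2 -0.66 ± 0.14) and Pfkfb3, which makes an activator of glycolysis, rose (log2 1.18 ± 0.24). With 1 array left out, Ldha stayed at -0.74 to -0.61 (lost whichever array was left out, at most 0.136 without diabetic 2) and Pfkfb3 at 0.96 to 1.32 (lost without normal 2 or 3 or diabetic 1, 2 or 3, at most 0.0992 without normal 3). The other Pfkfb3 probe set was at 0.96 (adjusted p = 0.114). The other 18 of 21 glucose uptake and glycolysis genes did not pass, Hk2 among them (adjusted p = 0.0987), and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.171). Of 5 ketone body genes, Oxct1, the enzyme that commits ketone bodies to oxidation in the heart, fell from 13679 ± 869 to 5697 ± 644 (log2 -1.27 ± 0.15, adjusted p = 0.00602), and Bdh1, beta-hydroxybutyrate dehydrogenase, fell at 2 probe sets (log2 -1.47 at the brighter and -2.28 at the other). The same 2 genes fell adjusted over the list alone (camera adjusted p = 0.0677, 0.0305 without normal 2, 0.0366 without diabetic 2 and 0.0486 without diabetic 3). Of 17 branched-chain amino acid genes, Bcat2, the mitochondrial aminotransferase (log2 -1.11 ± 0.17, adjusted p = 0.0122), and Ivd (log2 -0.72 ± 0.14) fell and none rose, with 3 fallen adjusted over the list alone (median -0.35, camera adjusted p = 0.00757, but adjusted p = 0.353 with an estimated correlation). Ivd stayed at -0.77 to -0.69 with each array left out but missed the threshold, at up to 0.097 without diabetic 2, and Bcat2 narrowly and only without diabetic 2.

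Oxidative phosphorylation genes shifted slightly down, with 1 of 61 fallen, Cox7a1 (log2 -1.25 ± 0.21, adjusted p = 0.0178, lost without normal 3 or diabetic 2 or 3, at most 0.0706 without diabetic 2), also adjusted over the list alone. The list's median was -0.12 (camera adjusted p = 0.013, but adjusted p = 0.626 with an estimated correlation). That call was lost without normal 1 (0.0864) and without diabetic 1 (0.116). None of 18 TCA cycle genes (adjusted p = 0.146), 13 glycogen genes (0.896) or 11 pyruvate dehydrogenase complex genes (0.348) passed, nor did any of 9 genes of polyol, hexosamine and pentose phosphate pathways (0.658). Adjusted over the list alone, 2 pyruvate dehydrogenase complex genes fell and none passed in the other 3 lists.

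Extracellular matrix genes gave the largest number of changes of any list, with 14 of 46 fallen and none risen. Adjusted over the list alone, 27 fell and 4 rose. Col3a1, a fibrillar collagen, fell from 10058 ± 948 to 2579 ± 525, which is 3.92-fold lower (log2 -1.97 ± 0.18, adjusted p = 0.00184). Col15a1, a basement membrane collagen, fell from 2013 ± 228 to 533 ± 49.7 (log2 -1.88 ± 0.15, adjusted p = 0.00129), and Serpinh1, the collagen chaperone, by 1.44. Col1a2 fell by 1.44 and Col1a1 by 1.24 on the log2 scale. Lum fell by 1.64 and Loxl1, of the collagen crosslinking family, by 1.83. Of those named here, Col1a1 (lost without normal 1 or 3 or diabetic 3, at most 0.0704 without normal 3) and Loxl1 were lost with arrays left out. Loxl1 was also lost with a pseudocount of 1 and with quantile normalization. Col4a1, chosen after its value was seen, fell only at a probe set not counted here (log2 -0.75, adjusted p = 0.0449). The list median was -0.51 (camera adjusted p = 5.38e-09, but adjusted p = 0.265 with an estimated correlation). Fibroblast markers moved with it, with 4 of 13 fallen, all 4 of them matrix genes of that list (Col1a1, Col1a2, Col3a1 and Lum), and 5 fallen and 1 risen adjusted over the list alone (median -0.36, camera adjusted p = 0.000785, but adjusted p = 0.265 with an estimated correlation). Beta-actin control probe sets were lower in every diabetic array than in every normal array, with differences of -0.76, -0.84 and -1.01 on the log2 scale for the 5', 3' and middle parts. They kept that sign under quantile and median scaling. Those of Gapdh differed by -0.04 to -0.13. The 3'/5' signal ratio ran from 1.18 to 1.41 for Gapdh and from 1.23 to 1.84 for beta-actin.

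Of 33 antioxidant and glutathione enzymes, catalase (Cat, log2 0.70 ± 0.14, adjusted p = 0.0322) and Mgst1 (log2 1.43 ± 0.29, adjusted p = 0.0377) rose and none fell, with 4 risen adjusted over the list alone. Txnrd1, a thioredoxin reductase, rose only at its dimmer probe set (log2 0.82, adjusted p = 0.0391), and the brighter one counted here was at 0.84 (adjusted p = 0.0584). The list median was 0.25 (camera adjusted p = 0.000785, but adjusted p = 0.353 with an estimated correlation). Cat stayed at 0.65 to 0.73 with each array left out but missed the threshold, at up to 0.113 without normal 3, and Mgst1 with most (lost without normal 1 or 3 or diabetic 2 or 3, at most 0.103 without diabetic 2). Among 22 other oxidoreductases, 5 rose and 3 fell (10 and 5 adjusted over the list alone). Cyp2e1, a cytochrome P450, rose from 459.8 ± 297 to 2116 ± 359 (adjusted p = 0.0465, lost without normal 2 or diabetic 1, 2 or 3, at most 0.128 without diabetic 2), and Cyp4b1 by 1.30 on the log2 scale. Aldh1a1, a retinaldehyde dehydrogenase, fell by 1.74, Aldh4a1 by 1.02 and Maob by 1.07. This list did not shift as a whole (adjusted p = 0.0541, and 0.0214 without normal 1, 0.0387 without diabetic 3).

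Of 33 calcium handling and calcium-binding genes, Jph2, which holds the junction between surface membrane and sarcoplasmic reticulum, fell from 3042 ± 552 to 1322 ± 81.4 (log2 -1.18 ± 0.17, adjusted p = 0.00974), and 5 fell adjusted over the list alone. The list median was -0.17 (camera adjusted p = 0.0016, but adjusted p = 0.265 with an estimated correlation). Atp2a2, the calcium pump of the reticulum, was at 52535 ± 7898 and 47961 ± 3981 (adjusted p = 0.733), and Pln, its inhibitor, at 27865 ± 3281 and 28872 ± 3691 (adjusted p = 0.905). Dimmer Atp2a2 probe sets were at -0.34 (adjusted p = 0.231) and -0.20 (adjusted p = 0.599) on the log2 scale. Of 16 potassium and sodium channel genes, Scn4b, a sodium channel subunit, fell (log2 -1.43 ± 0.21, adjusted p = 0.012), and 4 fell adjusted over the list alone (camera adjusted p = 0.306). Kcnd2, a potassium channel of the transient outward current, had a log2 difference of -0.79 ± 0.20 (adjusted p = 0.0702). Adra1b was the 1 of 14 adrenergic, angiotensin and endothelin genes to fall, also adjusted over the list alone (camera adjusted p = 0.896). Of 20 insulin signalling genes, Insr, the insulin receptor, rose (log2 0.89 ± 0.15, adjusted p = 0.019, lost without normal 2 or 3 or diabetic 2, at most 0.0746 without diabetic 2) and Igfbp5 fell, with 3 risen and 4 fallen adjusted over the list alone (camera adjusted p = 0.708). Igfbp3 rose only at its dimmer probe set (log2 1.57, adjusted p = 0.013), and the brighter one, which stands for it in the list, was at 1.40 (adjusted p = 0.0634).

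Of 33 genes of ubiquitin ligases, proteasome and autophagy, 4 rose and none fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.16). Bnip3, a mitochondrial protein of autophagy and cell death, rose from 4359 ± 1009 to 11177 ± 1448 (log2 1.37 ± 0.20, adjusted p = 0.0103), Trim63, a muscle ubiquitin ligase, by 0.91, Gabarapl1 by 0.96 and Ctsl, a lysosomal protease, by 1.05. Bnip3 passed with any 1 array left out, but not Trim63 (0.84 to 0.99, lost without normal 2 or 3 or diabetic 2 or 3, at most 0.0635 without diabetic 2), Ctsl (0.86 to 1.15, lost without normal 3 or diabetic 2 or 3, at most 0.0944 without diabetic 2) or Gabarapl1 (0.84 to 1.06, lost without normal 1, 2 or 3 or diabetic 1 or 3, at most 0.0837 without normal 3). Of 22 apoptosis and cell cycle inhibitor genes, Bnip3 and Bcl2l1 rose and none fell (4 risen adjusted over the list alone). Bcl2l1 encodes a protein known to block apoptosis (log2 1.24 ± 0.22, lost without normal 2 or 3 or diabetic 1 or 2, at most 0.0836 without normal 3). Its other probe set was at 0.39 (adjusted p = 0.343). That list had a median of 0.17 (camera adjusted p = 0.0195, but adjusted p = 0.265 with an estimated correlation), and 0.0566 without diabetic 1. Its call was also lost without the dim filter, the 1 shifted list of which this was so. Of 20 glucocorticoid responsive genes, Glul rose (log2 0.96 ± 0.18) and Fkbp4, a chaperone of the glucocorticoid receptor, fell (log2 -0.76 ± 0.16), with 6 risen and 1 fallen adjusted over the list alone. Its median was 0.39 (camera adjusted p = 0.013, but adjusted p = 0.577 with an estimated correlation, and 0.116 without diabetic 1). With 1 array left out, Glul stayed at 0.81 to 1.10 (lost without normal 2 or 3 or diabetic 1, 2 or 3, at most 0.0971 without diabetic 2) and Fkbp4 at -0.85 to -0.67 (lost whichever array was left out, at most 0.135 without normal 3). Of 3 Glul probe sets, 1 did not pass (0.59, adjusted p = 0.204). Klf9 and Cebpd, chosen after their values were seen, rose only at dimmer probe sets that are not counted here (log2 1.12 and 0.83). Of 9 proliferation genes, Ccnd2, a G1 cyclin, fell (log2 -1.25 ± 0.16, adjusted p = 0.00646), with 3 fallen adjusted over the list alone (median -0.25, camera adjusted p = 0.013, but adjusted p = 0.265 with an estimated correlation).

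Insig1, which restrains sterol synthesis, rose from 797 ± 139 to 2057 ± 168 (log2 1.36 ± 0.17, adjusted p = 0.00618), the 1 of 11 cholesterol synthesis genes to pass, also adjusted over the list alone (camera adjusted p = 0.151, and 0.0277 without normal 3). Of 30 heat shock and unfolded protein response genes, Sdf2l1 fell (log2 -0.75 ± 0.16, lost without normal 1, 2 or 3 or diabetic 2 or 3, at most 0.139 without normal 3), with 1 risen and 3 fallen adjusted over the list alone (camera adjusted p = 0.0588, 0.0482 without normal 2 and 0.0234 without diabetic 2). Of 12 clock genes, Cry2 rose (log2 0.66 ± 0.14, lost whichever array was left out, at most 0.137 without diabetic 2, and 0.59 with an adjusted p of 0.133 at its other probe set), with the same count adjusted over the list alone, and the list did not shift (0.415). No member of the 16 immediate early genes (0.761), 16 inflammation and complement genes (0.16) or 23 antigen presentation and interferon responsive genes (0.0821, and 0.00108 without diabetic 1) passed. Adjusted over the list alone, 1 gene of the last list rose and 2 fell, with none in the other 2 lists.

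Several genes often studied in the diabetic heart did not pass. Cd36, the fatty acid transporter, had a log2 difference of 0.51 ± 0.18 (adjusted p = 0.158), and Txnip, a glucose-responsive thioredoxin inhibitor, one of 0.83 ± 0.27 (adjusted p = 0.136), which was 0.48 without normal 3. Fbxo32, a muscle ubiquitin ligase, was at 0.67 ± 0.17 (adjusted p = 0.0691) and Slc2a1, the basal glucose transporter, at -0.60 ± 0.22 (adjusted p = 0.176, -0.39 without normal 3). Irs2 was at 0.64 ± 0.28 (0.96 without normal 1, 0.39 without normal 2), Cpt1a at 0.41 ± 0.20 (0.22 without normal 3) and Fabp3 at 0.07 ± 0.17. The dimmer Cpt1a probe set was at 0.58 (adjusted p = 0.118). Ppargc1a, a coactivator of mitochondrial genes, was at 0.13 ± 0.16, and the clock genes Dbp at 0.10 ± 0.45 and Bmal1 at -0.64 ± 0.34, where Dbp was 0.67 without normal 3 and Bmal1 -0.26 without diabetic 2.

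Markers of cell types other than fibroblasts and atrial cells showed few changes. Among 14 cardiomyocyte markers Myh6 was the 1 to fall (camera adjusted p = 0.188, 0.0404 without normal 3 and 0.023 without diabetic 2). Tie1 was the 1 of 13 endothelial markers to fall (log2 -0.94 ± 0.17, lost without normal 2 or 3 or diabetic 2 or 3, at most 0.0811 without normal 3, list adjusted p = 0.761), and Cidea the 1 of 7 adipocyte markers to rise (log2 0.83 ± 0.14, lost without normal 2 or 3 or diabetic 2 or 3, at most 0.0815 without normal 3, list adjusted p = 0.105). Of 5 tested skeletal muscle markers only Myh1 rose (list adjusted p = 0.451). Adjusted over the list alone, each of these 4 lists had the same count. No member passed among 10 smooth muscle and pericyte markers (0.761), 11 macrophage and monocyte markers (0.351) and 4 red blood cell markers (0.256), also adjusted over the list alone. The lymphocyte, neutrophil and platelet, mast cell, nerve and Schwann cell, and mesothelial lists had too few tested genes for a list test (2, 1, 2, 2 and 2), and none of those genes passed over all probe sets (1 platelet and 1 nerve marker fell adjusted over the list alone).

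**Figure D3:**
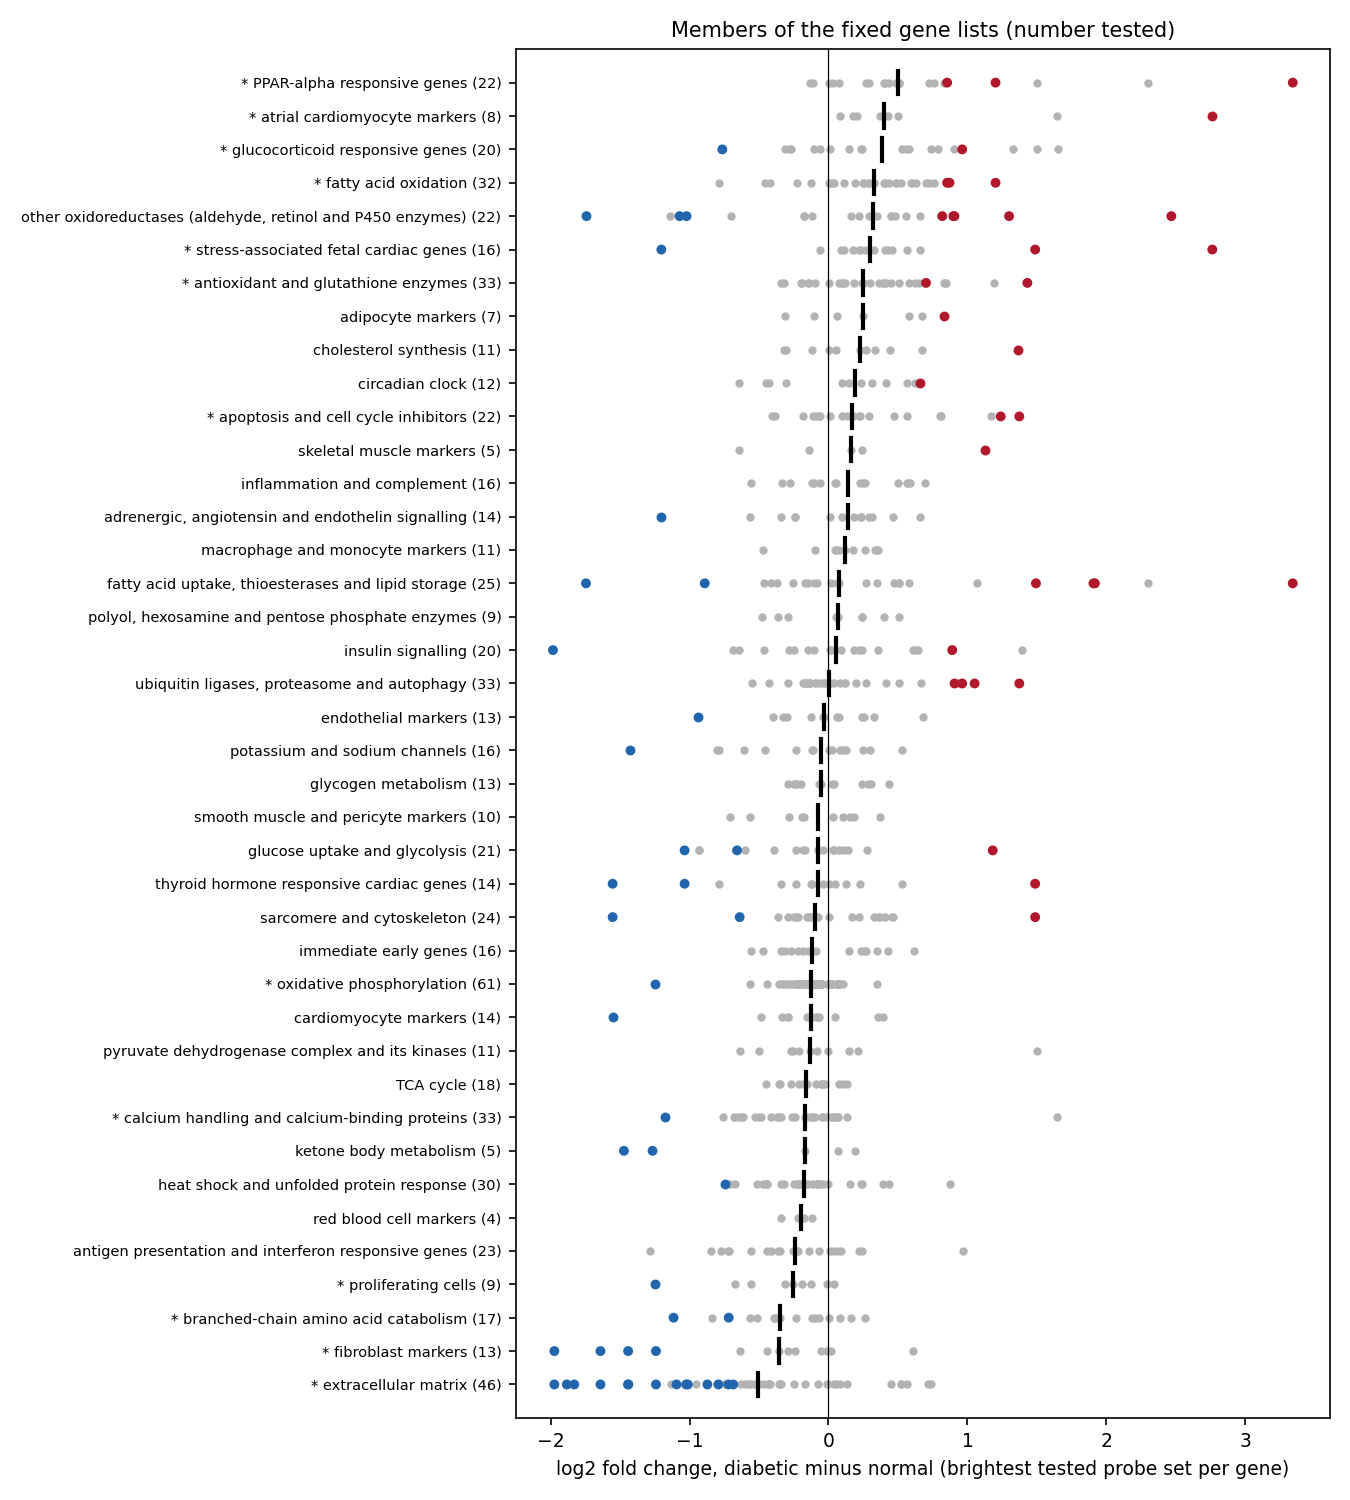
Log2 fold change of each tested member of the 40 tested gene lists, one row per list, with risen genes in red, fallen genes in blue, others in grey and the median as a black bar. A star marks the 13 lists with a camera adjusted p under 0.05 at the preset correlation, none of which passed with an estimated correlation.

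By camera with the preset correlation, 13 of 40 lists shifted, 7 up and 6 down. With an estimated correlation none passed after adjustment and 6 had an unadjusted p under 0.05, while fry called 9, of which 2 were up and 7 down. Fry did not call 6 of camera's 13, the fatty acid oxidation, PPAR-alpha, antioxidant, fetal cardiac and glucocorticoid lists among those up and oxidative phosphorylation among those down, and it called the ketone and heat shock lists. In 2 lists the median and camera's direction differed in sign, and in 3 the mean and camera's direction did. Of 51 changed genes with several tested probe sets, 48 had the same sign at all of them and 13 changed at all of them, and the exceptions in sign were Myh1, Rpl7 and Tmem64, the latter 2 named after their values were seen.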

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

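The control probe sets stood outside the comparison. AFFX-ThrX-5_at, which detects a bacterial transcript used as a control, was singled out because it was higher on every diabetic than on every normal array, with a log2 difference of 0.53. It was 1 of 57 control probe sets with that order, where chance gives 2.85. Another 5 were lower on every diabetic array, the 3 for beta-actin among them.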

How the results depend on the processing

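Every alternative named here was set before the data were examined, except the unfiltered fit with an intensity trend and Fisher's exact enrichment, which were chosen after seeing the data. The 274 changed probe sets became 18 without the dim filter, 437 with the filter at the 60th percentile, 527 with an intensity trend and 674 at a threshold of 0.1. Without the filter the share that rose was 44.4% against 52.2%. The added unfiltered fit with a trend gave 371, 231 of them among the 274, so the unfiltered count also depends on how the variance prior is set. Pseudocounts of 1 and 64 gave 220 and 402. Among the named genes lost with a pseudocount of 1 were Gal, Cyp2e1, Bdh1 (at the larger fall), Loxl1, G0s2, Ldha, Fhl2, Sdf2l1, Cry2 and Fkbp4. Loxl1 and Sdf2l1 were also lost with quantile scaling. Leaving out 1 array gave 100 to 202 changed probe sets, a risen share of 46.5% to 61.4% and 11 to 16 shifted lists. Fewer arrays also lower the power. None of the 274 changed sign in a setting that tested it, and the 60th percentile filter tested 210 of them. Of 67 changed named probe sets, 34 passed with any 1 array left out, and the losses were 28 without normal 3, 27 without diabetic 2, 25 without normal 2, 25 without diabetic 3, 18 without diabetic 1 and 16 without normal 1. Across all settings no named gene or list reversed, where a sign change of a value called in neither setting is not counted.

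Of the 13 shifted lists, 0 passed with an estimated correlation in limma's camera (6 lists had an unadjusted p under 0.05). Fry called 9 lists, 7 of them among the 13, and Fisher's exact enrichment called 7. Of the lists shifted in camera, Fisher's test called only matrix genes, fibroblast markers and PPAR-alpha responsive genes, and its other calls were lipid uptake, ketone, oxidoreductase and proteolysis genes. Among the 13 lists the estimated correlation reached 0.32 for PPAR-alpha responsive genes and 0.28 for fatty acid oxidation. It lay below the preset 0.01 for the calcium (-0.018), apoptosis (-0.028) and proliferation (-0.024) lists, so a higher correlation did not end those calls. The smaller degrees of freedom of camera with an estimated correlation raise p-values at any correlation, in these 3 lists too. For the other lists, the parts played by correlation and by degrees of freedom were not separated. With the replicate number as a block, 183 probe sets changed, 164 of them among the 274, and 13 lists shifted. Deviations of arrays with the same number correlated at 0.07, 0.01 and 0.02, and 2 of 3 normal arrays correlated best with their own number. With so few arrays these values cannot show whether the numbers pair the animals, and the labels do not say what the numbers mean. What the arrays limit is signal over background, since 6347 dim probe sets were not tested in the main comparison.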

Other observations

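The tests of array scaling, of RNA degradation and of signal shared with a paralog were chosen only after related values had been seen, and those of fibroblasts, atrial tissue, skeletal muscle and other splits of the arrays were set before their own values were seen. All were written down after the leading genes and the counts under several settings had been seen, so the patterns themselves were picked with the result in view. The Myh1 tests were for a time replaced by tests on normal 3 and then put back. The normal 3 values were also singled out after they were seen.

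Normal 3 differed from the other normal arrays in genes known to respond to fasting and to the clock. Its Txnip signal was 8758 against 18518 and 17841 in normal 1 and 2, and its Ucp3 signal 238 against 1096 and 883. Over the 22 PPAR-alpha responsive genes the median log2 deviation of normal 3 from the mean of the other 2 normal arrays was -0.39. For normal 1 and 2 it was 0.22 and 0.17, and for diabetic 1, 2 and 3 it was -0.20, 0.14 and 0.10. Against 10000 random lists matched on signal these lay at percentile 100, 99.76 and 0 for normal 1, 2 and 3 and at 0.25, 96.59 and 97.52 for diabetic 1, 2 and 3. Percentiles of 0 and 100 are limits of this measure and cannot be ranked. Each deviation is taken from the other 2 arrays of the group, so 1 odd array also moves its neighbours the other way. Clock genes varied on nearly every array. Dbp was at 124.9, 140.0 and 467.0 in normal 1, 2 and 3, and Nr1d1 at 186, 484 and 927. The median absolute deviation of the 12 clock genes lay at percentile 100, 98.2 and 100 of matched lists in normal 1, 2 and 3, and at 97.3, 90.1 and 99.3 in diabetic 1, 2 and 3. The labels give no time of sampling or feeding state. No explanation was tested for this pattern.

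The 15 tested collagens of the matrix list had a mean shift of -0.99 ± 0.12 (SE over arrays). The shift did not depend on the choice of scaling, at -0.98 after quantile normalization and -0.99 with arrays centred on their median. Both keep the assumption of a common signal level that the deposited values already carry, so they cannot test it. The median of all tested probe sets was -0.01, which that scaling holds near 0. RNA degradation is argued against, since the log2 ratio of 3' to 5' control signal differed by -0.022 ± 0.11. Fewer fibroblasts in the diabetic samples stay open, because the 5 fibroblast markers that are not matrix proteins (Thy1 lay below the dim filter) shifted by -0.32 ± 0.098, and that value minus 0.5 times the collagen shift was 0.17 ± 0.12. A lower transcript level per fibroblast in diabetes remains an untested biological hypothesis.

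The rise of Nppa by 2.76 ± 0.19 (SE over arrays) stayed at 2.76 after quantile normalization. It did not depend on the choice of scaling, but the assumption of a common signal level was not tested. Atrial tissue in the diabetic samples cannot be told apart, because Myl7, Sln and Myl4 together shifted by 0.75 ± 0.62 and these markers spread widely among arrays. Normal 1 held the highest Myl7 signal of all 6 arrays, 812, with an Nppa signal of 3816, while diabetic 3 held a Myl7 signal of 131 with an Nppa signal of 26650. A ventricular rise in diabetes was not tested apart from this.

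The 5 Myh1 probe sets had a mean shift of 0.66 ± 0.16, over 4 positive values and 1 negative (-1.02). Skeletal muscle in the diabetic samples is argued against, as the 11 other fast skeletal markers had a mean shift of 0.0043 ± 0.12. That mean covers members that went both ways, from -1.01 ± 0.62 for Tnnt3 to 0.64 ± 0.31 for Myh2, and 8 of the 11 lay below the dim filter. Signal shared with the paralog Myh7 stays open. The Myh7 probe sets shifted the same way, by 1.67 ± 0.25, and within groups the 2 signals correlated at 0.54 over 6 arrays, below the bound of 0.8 set for it.

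Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 274 changed probe sets and the highest other gave 1, so 1 split was as large. For shifted lists the real split gave 13 and the highest other 10. With 10 splits the share cannot go under 0.1, too few for a decision. The real split gave the largest mean difference for 12 of the 13 shifted lists and for 9 of the other 27. The exception among the 13 was the glucocorticoid list, where 2 of the 10 splits were as large, the real one included. Since the 13 were picked by their shift on the real split, their higher share is no separate support for the calls. Among the 6347 dim probe sets, limma called 0 in a fit of their own, with 399 at an unadjusted p under 0.05, where chance alone puts a share of 0.05 of them.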
